A study of Bos taurus with 12 samples.

How the data were processed

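Transcript levels were measured on the Affymetrix bovine genome GeneChip, a 3′ expression array on which each transcript is read by a set of short oligonucleotide probes. The 12 arrays hold RNA of placentas recovered at day 50 of pregnancy and of cultured fibroblasts. Per the labels' protocols, RNA was extracted with a column kit that keeps small RNA and was amplified and biotin-labelled with a 3′ IVT kit.

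The deposited table holds log2 values, 1 per probe set and array. Per the submitters' processing notes, the tools were GCRMA and limma. GCRMA corrects probe signals for background with a model of the probe sequence and then combines the probes of a set. The versions and settings are not given in the sources used here. The deposited log2 values ran from 2.34 to 14.19, and between 60.9% and 62.0% of the probe sets of an array lay under 4, close to the lower limit of the scale. A difference that ends near this limit is therefore understated. Raw probe signals were not used here, so the background correction could not be varied. The number of arrays limits the precision of every value.

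The table has 24128 probe sets, of which 112 are array controls and were left out. Of the other 24016, the platform annotation gives 13292 exactly 1 gene symbol, 86 several and 10638 none, and no probe set with several symbols was named. The Entrez identifier of 13263 of the 13292 was found in the RefSeq gene table, which changed no symbol, and 29 kept the platform's symbol. No genome was used, so no coordinates are given.

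Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes), with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. A probe set was tested when its log2 value was at least 4 in at least 3 arrays of the fit. The 3 comparisons between placentas used the 9 placenta arrays (9615 probe sets of 5491 genes), and the 2 comparisons with fibroblasts used all 12 arrays (10436 probe sets of 5899 genes). Where the dimmer group's mean was under 4, its level has only an upper bound. The fold is then written as "at least", from the brighter group's mean against 4.

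The comparisons, the tests, the 38 gene lists and the rule for named genes were chosen before the data were examined. For each placenta comparison the rule took probe sets with 1 symbol, an adjusted p under 0.05, a log2 difference of at least 1 and groups that did not overlap, and from these the 8 largest differences in each direction, 1 probe set per gene. Where none passed, it took the 5 lowest p-values in each direction. For the comparisons with fibroblasts it took 6 in each direction. It also took up to 4 members with the lowest p-values from each list described and every measured sex-linked gene, and it passed over uncharacterised symbols. Features named outside the rule are said to be chosen after their values were seen.

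The lists have 1102 members, of which 854 were found on the array. A gene in a list was represented by its probe set with the highest mean. Lists with at least 5 measured genes were tested with limma's camera, which asks whether a list is shifted against all other genes, with a preset inter-gene correlation of 0.01 and adjustment over the lists of a comparison. This gave 35 lists in each placenta comparison and 36 in each comparison with fibroblasts. The SCNT and IVP differences from AI share the AI arrays, so their overlap was set beside 100 simulations of unchanged groups, and after the results were seen also for each array left out. The direction of the donor cells was tested with contrasts that share no array, by an exact relabelling of the 6 arrays of the first contrast.

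The scripts were tested on simulated data made from the residual spread of the real arrays, with 200 probe sets changed, 50 of each size. The noise was drawn independently for each probe set and array, with no lower limit and no shift shared across an array. The shares below may therefore not hold for the real arrays. For SCNT against AI, 40%, 84%, 94% and 100% of the changes of 1, 2, 3 and 4 on the log2 scale were called. For IVP against AI these shares were 44%, 86%, 98% and 100%, and for SCNT against IVP 44%, 92%, 96% and 100%. For fibroblasts against AI they were 40%, 86%, 94% and 98%, and for SCNT against fibroblasts 40%, 84%, 94% and 96%. The calls that were false numbered 12 of 171, 3 of 167, 9 of 175, 3 of 162 and 8 of 165 in the same order.

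The alternatives were no filter, a filter at 6, quantile normalization, median centring, a variance trend with robust estimation, array weights, other sets of arrays in the fit, the replicate number as a block, 1 probe set per gene, other thresholds, and each array left out in turn. For the lists they also included an estimated correlation, limma's fry and the mean over a gene's probe sets. Leaving out AI replicate 3 and fibroblast replicate 1, with and without SCNT replicate 1, was added after the data were seen.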

Results

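The series compared bovine placentas at day 50 of pregnancy after day 7 blastocysts of 3 origins had been transferred to recipient cows. The blastocysts were conceived in vivo (AI), produced by fertilisation and culture in vitro (IVP), or made by somatic cell nuclear transfer (SCNT), in which the nucleus of a body cell replaces that of an oocyte. The fibroblasts that served as nuclear donors formed another group. Each group had 3 arrays, and between 9133 and 9395 probe sets per array had a log2 value of at least 4. The sample titles call the fibroblast arrays placenta while their source and protocol name donor fibroblasts, and they were grouped as fibroblasts. Nothing in the labels says that the samples of a group came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. No array repeated another. The closest pair, IVP replicates 1 and 2, correlated at r = 0.996 over all probe sets, with a median absolute difference of 0.14. The next closest pair crossed groups, with IVP replicate 2 and SCNT replicate 3 at r = 0.995. SCNT replicate 3 correlated at 0.962 and 0.984 with SCNT replicates 1 and 2. It was closer to every IVP array and to AI replicates 1 and 2 than to its own group.

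An array from each of 2 groups held transcripts of both placenta and fibroblasts. Fibroblast replicates 2 and 3 had 16 probe sets at 9 or more that lay under 4 in every IVP and SCNT placenta, and the reverse held for 72 probe sets. In AI replicate 3 all 16 fibroblast probe sets were above 4, with a median of 8.34, while AI replicates 1 and 2 each had 7 of the 16 above 4, with medians of 2.89 and 3.24. In fibroblast replicate 1 all 72 placenta probe sets were above 4, with a median of 9.18, against 2.45 and 2.54 in fibroblast replicates 2 and 3. These 2 arrays correlated with each other at r = 0.986. For example GPNMB, a transmembrane glycoprotein, was at 11.02 in AI replicate 3 and at 3.02 or lower in AI replicates 1 and 2, and PAG2, a pregnancy-associated glycoprotein of trophoblast, was at 13.36 in fibroblast replicate 1 and at 2.58 or lower in the other fibroblast arrays. Both arrays were kept in the planned tests, and some results are also given without them.

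**Figure D1:**
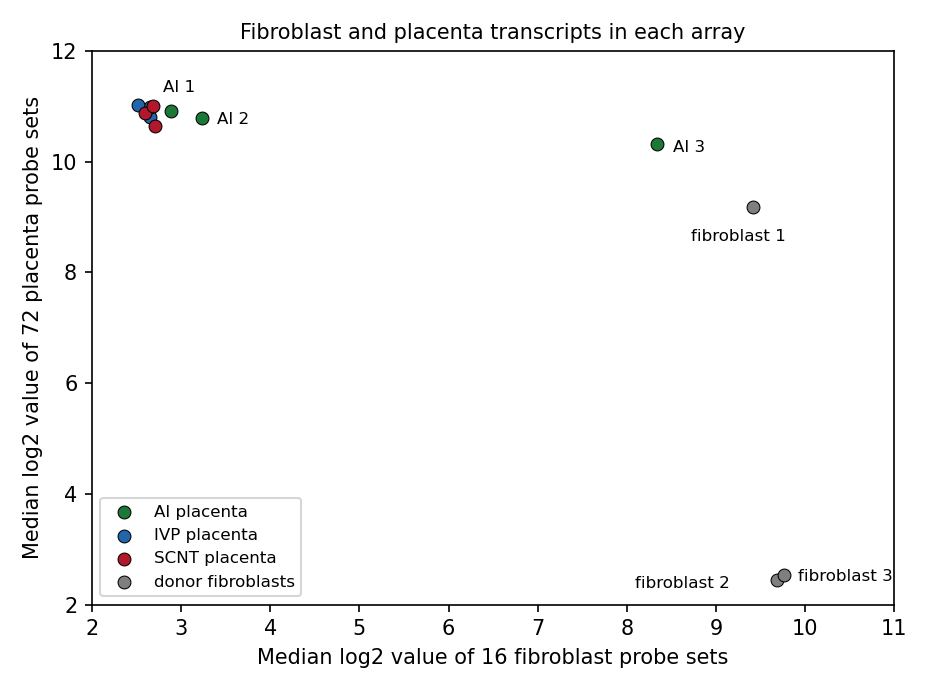
Median log2 value of 16 fibroblast probe sets (x axis) and of 72 placenta probe sets (y axis) in each of the 12 arrays, 1 point per array, coloured by group. AI replicate 3 (8.34 and 10.3) and fibroblast replicate 1 (9.42 and 9.18) are high on both axes, and the other 10 arrays are high on one.

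The arrays also differed in XIST, the transcript that silences an X chromosome in female cells. XIST was at 8.89, 8.90 and 6.86 in AI replicates 1, 2 and 3, at 8.58 in IVP replicate 3 and at 5.53 in fibroblast replicate 1. It was at 2.84 or lower in the other 7 arrays, which include all 3 SCNT placentas. The Y-linked ZFY was at the lower limit of the scale in all 12 arrays and so does not separate them. The SCNT and AI groups therefore differ in XIST as well as in embryo origin.

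The first comparison asked how placentas of cloned conceptuses differed from those of in vivo derived ones. The largest called decreases in SCNT placentas included genes of the matrix and of contractile cells. TNC, which encodes the matrix glycoprotein tenascin-C, was at 2.73 ± 0.03 (SD, n = 3) in SCNT and 7.99 ± 1.71 (SD, n = 3) in AI placentas, at least 15.8-fold lower (adjusted p = 0.0175, limma). ACTA2, smooth muscle actin, was lower at 4.98 ± 1.21 against 8.98 ± 0.95 (adjusted p = 0.0263). In the other direction SERPINB1, an inhibitor of neutrophil proteases, was 3.52-fold higher, at 11.02 ± 0.18 against 9.20 ± 0.08 (adjusted p = 0.00518), while its other tested probe set was higher by 0.85 without passing (adjusted p = 0.317).

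CDH11, a cadherin of mesenchymal cells, fell at least 15.4-fold in SCNT placentas, and its other tested probe set differed by −2.43 without passing (adjusted p = 0.0507). TAGLN, an actin-binding protein of smooth muscle, fell at least 6.39-fold. CCL2, a chemokine that attracts monocytes, fell at least 5.77-fold, and CTSS, a lysosomal protease of antigen processing, fell from 8.30 ± 1.10 to 4.85 ± 0.81 (SD, n = 3). PLAC8A, first described as a placenta-specific gene, fell at least 9.80-fold and FMR1NB at least 7.70-fold. Of the genes that rose, C4A, which encodes complement component 4, was 5.03-fold higher at 6.47 ± 0.40 against 4.14 ± 0.33. BCLAF1, PRELID2 and the sulfatase gene ARSL were 3.95-fold, 3.38-fold and 3.53-fold higher. RIOK3, an atypical kinase, was at least 2.56-fold higher and HSPB3, a small heat shock protein, at least 1.76-fold. A probe set annotated as EED, a polycomb protein, was at least 4.82-fold higher, but the platform gives this symbol to 23 probe sets, so the gene behind it is uncertain. Of the 18 others tested, 1 passed, a probe set of the same cluster with a difference of 2.48 (adjusted p = 0.0113), and 7 went the other way. The other tested probe sets of BCLAF1 and RIOK3 did not follow, with differences of 0.14 in both (adjusted p = 0.597 and 0.614), so the changes of these 2 genes are uncertain as well. The adjusted p-values of these 13 genes lay between 0.0175 and 0.0472. Over the 10 to 16 alternatives run for each of the 16 genes, 13 ended the call of RIOK3, 11 those of BCLAF1 and PRELID2, 10 those of ARSL, CDH11 and FMR1NB, and 9 those of ACTA2 and CTSS. For EED and C4A 7 did so, for CCL2 6, for PLAC8A 5, for HSPB3 and TAGLN 4, for TNC 3 and for SERPINB1 2. TNC, TAGLN and CCL2 had only 10 alternatives and HSPB3 11. The first 3 met the filter only through the AI arrays, so they were not tested when any AI array was left out. Their calls were thus never tried without AI replicate 3, and their counts cannot be compared with those of the other genes.

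**Figure D2:**
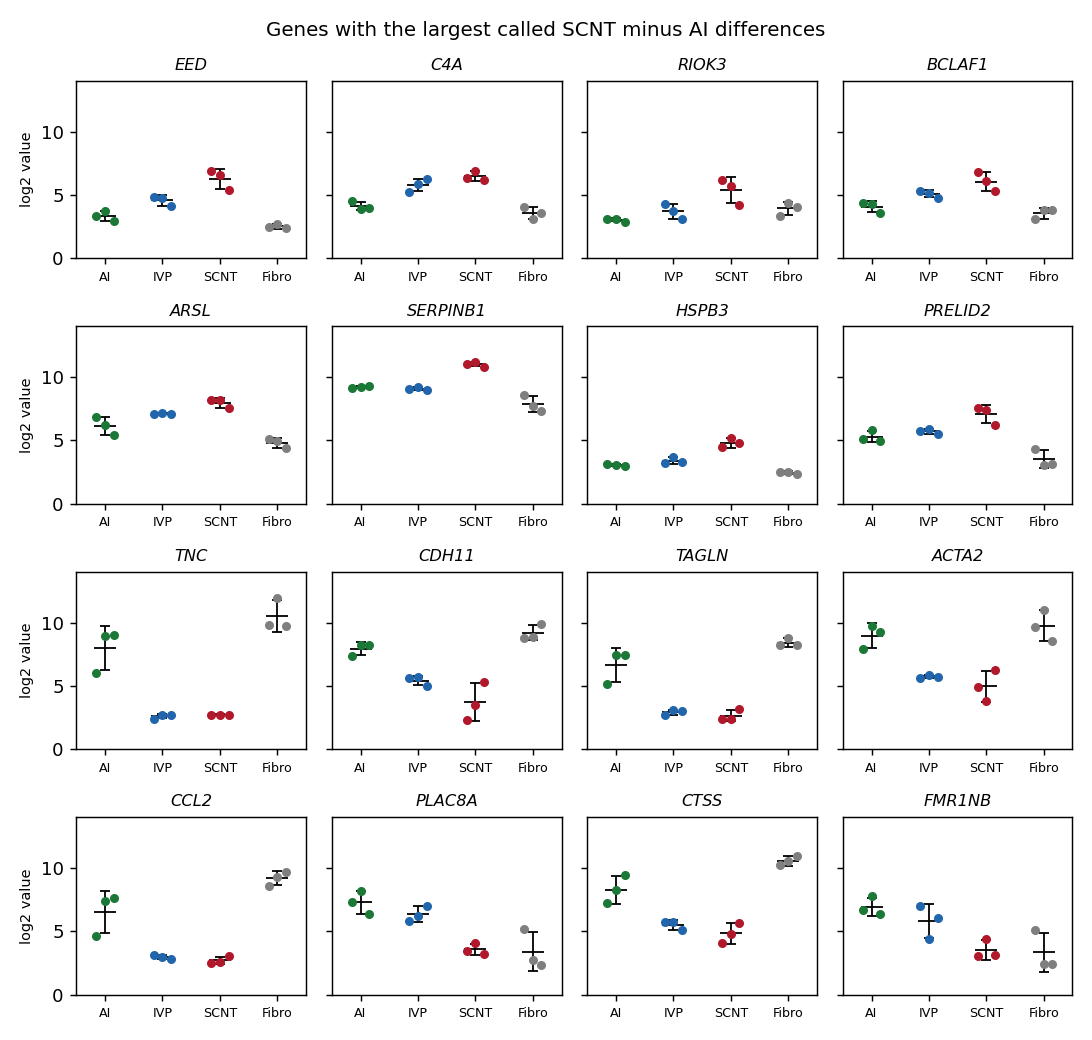
Log2 value (y axis) of the 16 genes with the largest called differences between SCNT and AI placentas, in each array of the 4 groups (x axis, Fibro: donor fibroblasts), with the mean and SD (bars, n = 3). SERPINB1 lies between 10.82 and 11.17 in SCNT placentas and between 8.96 and 9.28 in the other placentas, while TNC lies between 2.43 and 2.74 in all SCNT and IVP placentas and between 6.01 and 9.04 in AI placentas.

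Of the 35 gene lists tested, 7 were shifted lower and 1 higher in SCNT placentas. Fibrillar collagens and other matrix genes were lower in all 24 measured members, of which 5 fell in the test over all probe sets and 16 when adjusted over the list alone, with a median of −2.14 (camera adjusted p = 3.61e-09, and adjusted p = 0.722 with an estimated correlation). Besides TNC, the collagen subunit COL5A2 fell from 9.52 ± 0.44 to 6.76 ± 1.05 and COL1A2 from 12.68 ± 0.15 to 10.57 ± 0.90, and the proteoglycan DCN from 12.09 ± 0.19 to 9.92 ± 0.57. The other tested probe set of COL1A2 differed by only −0.47 without passing (adjusted p = 0.203), and 12 of 16 alternatives ended its call, as did 11 of 15 for COL5A2 and 9 of 15 for DCN. Of 14 markers of fibroblasts and mesenchyme, 2 fell and 10 when adjusted over the list alone (median −2.14, camera adjusted p = 2.82e-05, adjusted p = 0.722 with an estimated correlation). By design this list and the matrix list have COL1A1, COL1A2, COL3A1, LUM, DCN, POSTN, LOX and FBLN1 in common. They are therefore not separate evidence. Of 7 markers of smooth muscle and pericytes, ACTA2 and TAGLN fell, and 6 when adjusted over the list alone (median −2.15, camera adjusted p = 0.000288, adjusted p = 0.722 with an estimated correlation), while TPM2 was at 5.68 ± 1.08 against 8.31 ± 0.89 without passing. These lists also contain genes that donor fibroblasts express, and AI replicate 3 carried fibroblast transcripts. Without that array their medians were −1.78, −1.64 and −1.76, with camera adjusted p-values of 6.03e-09, 5.67e-06 and 0.00178. None of their members was then called, and each list had an adjusted p = 0.761 with an estimated correlation.

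Genes of protein synthesis and respiration were slightly lower as groups. The 36 cytosolic ribosomal proteins had a median of −0.55, 35 of them negative and none passing singly (camera adjusted p = 1.59e-06, adjusted p = 0.722 with an estimated correlation). RPLP0 was at 11.60 ± 0.27 against 12.26 ± 0.14. The mean difference of the list was −0.54 with all arrays, −0.31 without SCNT replicate 1 and −0.75 without SCNT replicate 3, and SCNT replicate 1 was also the array with the lowest 99th percentile (10.61, against 10.85 to 11.04 in the others). The 48 genes of oxidative phosphorylation had a median of −0.46, 42 of them negative and none passing singly (camera adjusted p = 0.000421, adjusted p = 0.759 with an estimated correlation). Its mean difference was −0.44 with all arrays and ran from −0.64 to −0.22 over the alternatives. Neither list had a member that passed when adjusted over the list alone. Among 22 genes of antioxidant defence, GSTO1, a glutathione transferase, fell from 8.19 ± 0.69 to 6.07 ± 0.37, and 5 fell when adjusted over the list alone (median −0.78, camera adjusted p = 0.00806, adjusted p = 0.722 with an estimated correlation). Of 7 genes of antigen presentation CTSS fell, and 4 when adjusted over the list alone (median −1.80, camera adjusted p = 0.0140, adjusted p = 0.722 with an estimated correlation). Without AI replicate 3 the median of this list was −1.30 (camera adjusted p = 0.0325) and no member was called. Of 17 alternatives, 4 ended its call. The MHC class I gene BOLA, whose paralogs are nearly identical, was at 4.97 ± 0.09 against 6.89 ± 1.07 without passing. The 33 genes of cell cycle and DNA replication were higher by a median of 0.29 with none passing singly or over the list alone (camera adjusted p = 0.00806, adjusted p = 0.770 with an estimated correlation). The cell cycle shift did not pass without AI replicate 3 (median 0.10, camera adjusted p = 0.263), and 6 of 17 alternatives ended its call.

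The lists of genes of trophoblast, the epithelium of the placenta, did not pass camera, which does not exclude a shift. The 6 lactogen and prolactin-related genes had a median of 0.10 (camera adjusted p = 0.263), and 1 was higher when adjusted over the list alone. Of 17 pregnancy-associated glycoproteins, a family of near-identical paralogs, PAG15 fell from 8.72 ± 0.48 to 5.41 ± 0.50 (adjusted p = 0.0263), and 3 fell when adjusted over the list alone (median −0.09, camera adjusted p = 0.447). Of 16 trophoblast transcription factors and keratins, OVOL1 rose by 0.90 (adjusted p = 0.0412), and 2 were higher and 2 lower when adjusted over the list alone (median 0.05, camera adjusted p = 0.647). Of 22 imprinted genes, DCN fell, and 3 were higher and 8 lower when adjusted over the list alone (median −0.51, camera adjusted p = 0.185). Among sex-linked genes, XIST was at 2.58 ± 0.24 in SCNT and 8.22 ± 1.17 in AI placentas (adjusted p = 0.0640) and KDM6A at 4.65 ± 0.52 and 5.89 ± 0.35 (adjusted p = 0.0692). EIF2S3 was at 10.78 ± 0.38 and 10.59 ± 0.10 (adjusted p = 0.556).

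In all, limma called 187 of 9615 probe sets between SCNT and AI placentas, 89 higher and 98 lower, of which 171 differed at least 2-fold, and 3105 had an unadjusted p under 0.05. The count depended on single arrays: it was 0, 6 and 3146 without SCNT replicates 2, 1 and 3, 321, 3 and 8 without AI replicates 1, 2 and 3, and 28, 20 and 58 without IVP replicates 1, 2 and 3, with 1907 probe sets at an unadjusted p under 0.05 where it was 0. Without AI replicate 3, all 172 of the calls that were still tested kept their direction and an unadjusted p under 0.05, with a median ratio of 0.939 to the difference with it. The calls were picked with that array included and the other arrays were reused, so this was largely fixed in advance. Calls that met the filter only through the AI arrays, such as TNC, TAGLN and CCL2, were no longer tested.

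**Figure D3:**
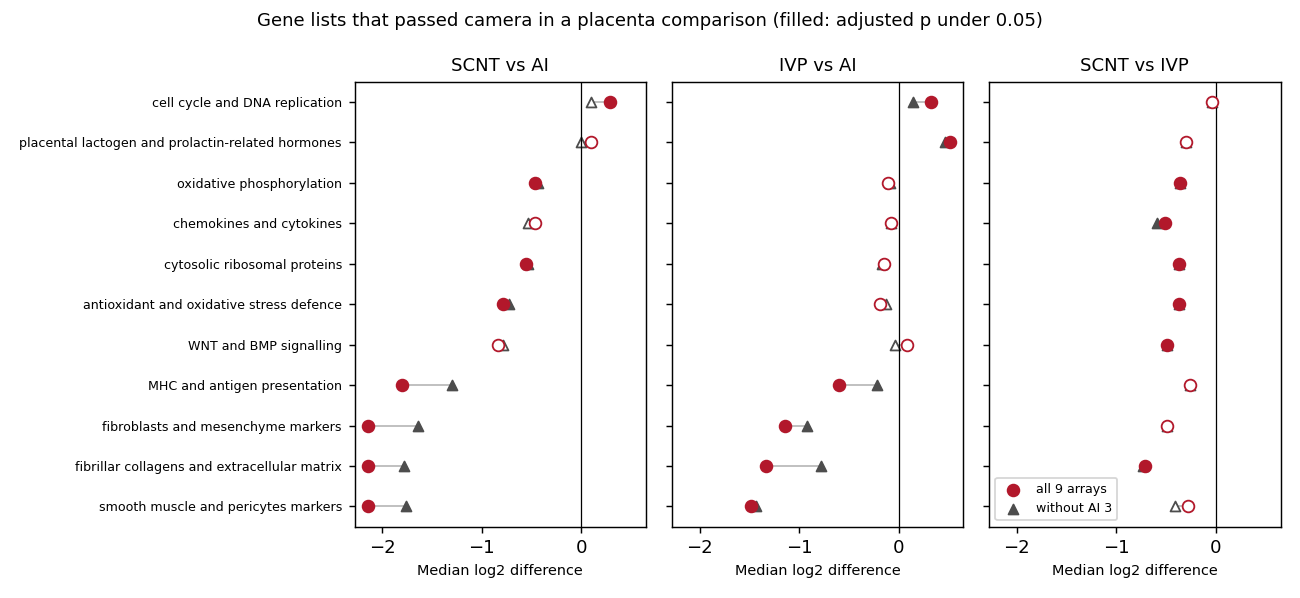
Median log2 difference (x axis) of the gene lists that passed camera in at least 1 of the 3 placenta comparisons (1 panel each), with all 9 placenta arrays (circles) and without AI replicate 3 (triangles); filled symbols had an adjusted p under 0.05. The matrix list lies at −2.14, −1.33 and −0.71 in the 3 panels, and no list passed with an estimated correlation.

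The comparison of IVP with AI placentas asked about in vitro production without nuclear transfer. No named gene passed the test. The lowest p-values among lower genes belonged to TNC, at 2.64 ± 0.18 (SD, n = 3) in IVP and 7.99 ± 1.71 (SD, n = 3) in AI placentas (adjusted p = 0.0847, limma), TAGLN at 2.93 ± 0.21 against 6.68 ± 1.34, PTGDS, a prostaglandin synthase, at 4.25 ± 0.38 against 6.69 ± 0.67, the co-chaperone BAG3 at 4.91 ± 0.22 against 6.71 ± 0.62, and SERF2 at 3.72 ± 0.20 against 4.91 ± 0.31. Among higher genes they belonged to TIPARP, an ADP-ribosyltransferase, at 7.38 ± 0.22 against 5.88 ± 0.12 (adjusted p = 0.0938), and SFXN1, a mitochondrial serine carrier, at 10.28 ± 0.36 against 8.86 ± 0.18. They were followed by the receptor gene TGFBR1 at 4.82 ± 0.30 against 3.35 ± 0.44, C4A at 5.79 ± 0.49 against 4.14 ± 0.33, and the deubiquitinase gene USP12 at 6.46 ± 0.43 against 4.88 ± 0.49. The adjusted p-values of these 10 genes reached 0.156.

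As groups, the matrix and contractile genes were lower in IVP placentas as well, in 4 lists shifted lower and 2 higher of 35. The 24 matrix genes had a median of −1.33, 23 of them negative, and 7 were lower when adjusted over the list alone (camera adjusted p = 1.87e-09, adjusted p = 0.679 with an estimated correlation). The 7 smooth muscle markers had a median of −1.48, with 6 lower when adjusted over the list alone (camera adjusted p = 9.36e-06, adjusted p = 0.646 with an estimated correlation), and ACTA2 was at 5.75 ± 0.13 against 8.98 ± 0.95. The 14 fibroblast markers had a median of −1.14, with 3 lower when adjusted over the list alone (camera adjusted p = 3.36e-05, adjusted p = 0.751 with an estimated correlation). The 7 genes of antigen presentation had a median of −0.60, with 2 lower when adjusted over the list alone (camera adjusted p = 0.0108, adjusted p = 0.751 with an estimated correlation). In the other direction, the 33 cell cycle genes had a median of 0.33, 30 of them positive and none passing over the list alone (camera adjusted p = 1.35e-06, adjusted p = 0.751 with an estimated correlation). The 6 lactogen and prolactin-related genes had a median of 0.52, all positive, with 2 higher when adjusted over the list alone (camera adjusted p = 0.00321, adjusted p = 0.646 with an estimated correlation). PRP9 was at 8.82 ± 0.68 in IVP and 7.27 ± 0.94 in AI placentas. Without AI replicate 3 these 6 lists passed with the preset correlation but not with an estimated one (adjusted p = 0.618), and the medians of the matrix, antigen presentation and cell cycle lists were −0.78, −0.21 and 0.15. The number of lists that passed camera with the preset correlation was then 11. With all arrays, none of the 35 lists passed with fry.

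limma called 1 probe set between IVP and AI placentas, and 1124 had an unadjusted p under 0.05. It was Bt.2120.1.S1_at, which has no gene symbol here and was chosen after its values were seen, at 6.32 ± 0.14 in IVP and 3.14 ± 0.47 in AI placentas (at least 4.99-fold, adjusted p = 0.0362). The count was 0 without AI replicates 2 or 3, IVP replicates 1 or 2 and SCNT replicates 1 or 2, and 5 without AI replicate 1, with 618 probe sets at an unadjusted p under 0.05 without AI replicate 3. XIST was at 4.43 ± 3.59 and 8.22 ± 1.17, KDM6A at 5.60 ± 0.56 and 5.89 ± 0.35, and EIF2S3 at 10.51 ± 0.24 and 10.59 ± 0.10, with adjusted p-values of 0.380, 0.762 and 0.924.

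SCNT and IVP placentas were then compared directly, which tests whether their differences from AI placentas differ. SERPINB1 was 3.82-fold higher in SCNT placentas, at 11.02 ± 0.18 against 9.08 ± 0.13 (SD, n = 3; adjusted p = 0.00297, limma). ADD3, which encodes the membrane skeleton protein adducin 3, was 10.4-fold lower, at 5.16 ± 0.17 against 8.54 ± 0.12 (adjusted p = 0.00732). DEFB4A, a beta-defensin whose probe set can be shared with related genes, was 4.93-fold lower, at 4.59 ± 0.17 against 6.90 ± 0.08 (adjusted p = 0.00402). The level of each of these 3 genes in AI placentas was close to that in IVP placentas, at 9.20 ± 0.08 for SERPINB1, 8.13 ± 0.79 for ADD3 and 6.37 ± 0.37 for DEFB4A. Their other tested probe sets differed by 1.29, −0.94 and −1.42 in the same order and did not pass (adjusted p = 0.309, 0.308 and 0.308).

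These genes and 2 probe sets with no symbol here, chosen after their values were seen, made up the 5 calls among 9615 probe sets, 2 higher and 3 lower, and 1533 had an unadjusted p under 0.05. Bt.15801.1.A1_at was at least 6.38-fold lower in SCNT placentas (3.34 ± 0.22 against 6.67 ± 0.53, adjusted p = 0.00297) and Bt.17073.1.S1_at was 3.27-fold higher (7.43 ± 0.36 against 5.72 ± 0.12, adjusted p = 0.0267). XIST was at 2.58 ± 0.24 and 4.43 ± 3.59, KDM6A at 4.65 ± 0.52 and 5.60 ± 0.56, and EIF2S3 at 10.78 ± 0.38 and 10.51 ± 0.24, with adjusted p-values of 0.467, 0.308 and 0.495. Without IVP replicate 1, 2 or 3 or SCNT replicate 2 the count was 3, and without SCNT replicate 3 it was 1757.

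Of 35 lists, 6 were shifted lower in SCNT than in IVP placentas, all without a called member and all with an adjusted p = 0.833 when the correlation was estimated. The 36 ribosomal proteins had a median of −0.38 with 35 negative (camera adjusted p = 2.95e-05), the 48 genes of oxidative phosphorylation a median of −0.36 (0.00499), and the 24 matrix genes a median of −0.71 (0.0281). RPL24 was at 11.09 ± 0.67 in SCNT and 11.77 ± 0.05 in IVP placentas, NDUFA2, a subunit of complex I, at 8.02 ± 0.56 and 9.16 ± 0.13, and FN1, fibronectin, at 9.68 ± 1.78 and 11.72 ± 0.59. The 22 antioxidant genes had a median of −0.37 (0.0392), the 14 genes of WNT and BMP signalling a median of −0.49 (0.0485), and the 9 chemokines and cytokines a median of −0.51 with all 9 negative (0.0485). IL6, an inflammatory cytokine, was at 5.71 ± 0.97 and 7.68 ± 0.33. Only the WNT and BMP list had members that passed when adjusted over the list alone, 3 of them, all lower. The shifts were uneven over the SCNT placentas, and SCNT replicate 3 lay near the IVP level in several genes, with RPL24 at 10.42, 11.10 and 11.75 and FN1 at 8.23, 9.13 and 11.66 in SCNT replicates 1, 2 and 3. The mean difference of the ribosomal proteins was −0.15 without SCNT replicate 1 and −0.59 without SCNT replicate 3, and that of oxidative phosphorylation was −0.13 without SCNT replicate 1 and no longer passed. The WNT and BMP list did not pass without AI replicate 3 (adjusted p = 0.0697). Of 17 alternatives, 12 ended the call of the WNT and BMP list, 10 that of the chemokines and cytokines, 9 that of the antioxidant genes, 5 that of the matrix genes, 4 that of oxidative phosphorylation and 2 that of the ribosomal proteins. The number of lists that passed was 4, 2 and 4 without IVP replicate 1, IVP replicate 2 and SCNT replicate 1.

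The SCNT and IVP differences from AI placentas were more alike than the shared AI arrays alone gave in simulations. Over 9615 probe sets, which are not independent, they correlated at r = 0.723 (Spearman's rho = 0.628), and 71.4% had the same sign, against a simulated 66.7%. The shared AI arrays alone gave a mean r of 0.499 in simulations, with a range of 0.470 to 0.527. The covariance of the differences was 0.257 against a simulated 0.0459. At an unadjusted p under 0.05, 385 probe sets were higher and 362 lower in both, where independent lists would share 106 and 76.8 and unchanged groups shared 51.0 and 51.2, and 3 went opposite ways. Neither count is a full baseline, because independent lists ignore the shared AI arrays and the unchanged groups held no true differences. The simulations also gave the AI arrays the spread pooled over the 3 groups. AI replicate 3 lay apart from AI replicates 1 and 2 (r = 0.967 and 0.972), so the simulated r may be too low. The overlap of the calls was 1 probe set. The 3 AI arrays cannot be split into parts of 2, so some of the excess may come from them. Without AI replicate 3 the correlation was 0.691, where simulations with the remaining 2 AI arrays gave 0.600 with a range of 0.567 to 0.623, and the covariance was 0.190 against a simulated 0.0570. These later simulations were added after the results were seen.

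Donor fibroblasts and AI placentas differed in much of the array, as the trophoblast products show. All 6 lactogen and prolactin-related genes and all 17 pregnancy-associated glycoproteins were lower in fibroblasts. The largest decreases were in PAG2, S100G, the calcium carrier calbindin-D9k, HBB, the adult beta globin, PLET1, the prolactin-related PRP1 and PAG11, with log2 differences between −7.79 and −7.32 (adjusted p between 0.00920 and 0.0136, limma). Their SDs in fibroblasts lay between 5.43 and 6.29 (n = 3), because fibroblast replicate 1 carried placental transcripts. Without that array and AI replicate 3 the differences lay between −11.46 and −10.60. The remaining fibroblast levels lay under 4 and so have only an upper bound. The other tested probe set of PLET1 differed by only −2.18 and did not pass (adjusted p = 0.179). The largest increases were in GPNMB, CDH13, a cadherin, XDH, xanthine dehydrogenase, TFPI2, a protease inhibitor of the matrix, SFRP4, a secreted WNT inhibitor, and SST, somatostatin, with log2 differences between 5.14 and 6.17 (adjusted p between 0.00190 and 0.0114) and SDs in AI placentas between 2.15 and 4.83. Without AI replicate 3 these 6 differences lay between 6.38 and 8.95. GPNMB, CDH13, XDH and TFPI2 lay under 4 in AI replicates 1 and 2, so their level there has only an upper bound. CDH13 was at 10.67, 10.66 and 10.95 in the fibroblast arrays and at 2.60, 2.81 and 9.47 in AI replicates 1, 2 and 3.

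Of 36 lists, 9 were shifted lower in fibroblasts and 1 higher, each with an adjusted p = 0.644 with an estimated correlation. Besides the 6 hormone genes (median −6.67, camera adjusted p = 0.00619, and −9.49 without the 2 mixed arrays) and the 17 glycoproteins (median −5.38, 1.21e-05, and −7.53 without them), these included 16 trophoblast transcription factors and keratins, 12 lower and 1 higher (median −2.47, 0.000241). ETS2, a transcription factor, was at 4.04 ± 1.07 against 6.82 ± 0.47. All 6 measured trophoblast secreted products were lower (median −4.26, 0.00423), with the oestrogen sulfotransferase SULT1E1 at 4.84 ± 3.65 against 10.92 ± 0.60. Of 34 cell cycle genes 24 were lower and 2 higher (median −1.45, 1.93e-05), with CDK2 at 3.53 ± 0.61 against 5.51 ± 0.41 and CCND1, cyclin D1, higher at 7.00 ± 0.31 against 4.49 ± 1.11. Of 11 genes of ion and water transport 9 were lower and 1 higher (median −2.19, 0.00261), and of 10 endothelial markers 8 were lower and 1 higher (median −2.30, 0.00423). All 7 erythroid genes were lower (median −2.73, 0.00783). Of 18 genes of the unfolded protein response 10 were lower and 2 higher (median −0.58, 0.0358), a shift that did not pass without the mixed arrays (adjusted p = 0.104). Of 17 genes of cholesterol synthesis 11 were higher and none lower (median 0.68, 0.00453), with SQLE, squalene epoxidase, at 10.10 ± 0.34 against 8.51 ± 0.43. Adjusted over the list alone, the counts were the same except for cell cycle, with 29 lower, and cholesterol synthesis, with 12 higher and 1 lower.

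limma called 5450 of 10436 probe sets between fibroblasts and AI placentas, 2823 higher and 2627 lower in fibroblasts, and 3507 of them differed at least 2-fold. Without AI replicate 3 and fibroblast replicate 1 the count was 5137, and 4723 of these were among the 5450. XIST was at least 18.6-fold lower in fibroblasts (3.41 ± 1.83 against 8.22 ± 1.17, adjusted p = 0.0193), KDM6A fell 3.01-fold (adjusted p = 0.00527) and EIF2S3 was at 10.34 ± 0.22 against 10.59 ± 0.10 (adjusted p = 0.354).

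SCNT placentas were set against the fibroblasts to see how far the cloned tissue lay from the donor cells. The largest increases in SCNT placentas were in PAGE4, the imprinted genes PHLDA2 and PEG3, S100G, PRP1 and SSLP1, a secreted protein of trophoblast, with log2 differences between 7.45 and 7.67 (adjusted p between 0.00124 and 0.00949, limma) and between 10.03 and 11.08 without the 2 mixed arrays. The levels of these 6 genes in fibroblast replicates 2 and 3 lay under 4 and so have only an upper bound. Of 3 other tested probe sets of PEG3, 1 did not pass, with a difference of 1.00 (adjusted p = 0.0602). PHLDA2 was at 13.19 ± 0.01 (SD, n = 3) in SCNT placentas and at 2.53 or lower in fibroblast replicates 2 and 3. GPNMB was at least 198-fold lower in SCNT placentas, at 2.38 ± 0.02 against 11.63 ± 0.16 (adjusted p = 0.000806). S100A4, a calcium-binding protein of fibroblasts, fell 362-fold and MMP2, a matrix protease, fell 232-fold, and CDH13, TFPI2 and TNC were at least 109-fold, 81.4-fold and 91.9-fold lower (adjusted p between 0.000118 and 0.000609).

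Of 36 lists, 7 were shifted higher and 6 lower in SCNT placentas, but none passed with an estimated correlation, where the adjusted p was 0.699 for oxidative phosphorylation, 0.672 for the ribosomal proteins and 0.648 for the other 11 lists. The higher ones were the 6 hormone genes, all higher (median 7.04, camera adjusted p = 0.0140), the 17 glycoproteins, 15 higher (camera adjusted p = 0.000325), the 16 trophoblast transcription factors and keratins, 12 higher and 2 lower (median 2.49, 0.00119), and the 6 secreted products, 5 higher (median 3.42, 0.0140). The 11 genes of ion and water transport, 9 higher and 1 lower (median 1.97, 0.0140), the 34 cell cycle genes, 27 higher and 2 lower (median 1.73, 4.34e-05), and the 10 endothelial markers, 7 higher and 1 lower (median 1.74, 0.0166), shifted the same way. TFRC, the transferrin receptor, was at 8.86 ± 0.67 in SCNT placentas and 3.71 ± 2.01 in fibroblasts, and the endothelial gene PECAM1 was higher by 2.76. Of 26 matrix genes 20 were lower and 2 higher (median −2.87, 0.000325), and of 16 fibroblast markers 12 were lower and 2 higher (median −2.39, 0.0140). VIM, the filament protein vimentin, was at 8.77 ± 1.44 and 13.71 ± 0.23, and FAP, fibroblast activation protein, at 2.72 ± 0.33 and 9.65 ± 0.66. Of 36 ribosomal proteins 28 were lower (median −0.73, 0.00119), of 26 antioxidant genes 17 were lower and 4 higher (median −1.45, 0.0249), of 48 genes of oxidative phosphorylation 24 were lower and 1 higher (median −0.57, 0.0249), and of 8 genes of antigen presentation 6 were lower (median −2.81, 0.0249). Adjusted over the list alone the counts were the same except for the ribosomal proteins, with 30 lower, the antioxidant genes, with 18 lower, and oxidative phosphorylation, with 23 lower.

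limma called 6700 of 10436 probe sets between SCNT placentas and fibroblasts, 3226 higher and 3474 lower in SCNT placentas, and 4642 of them differed at least 2-fold. Without the 2 mixed arrays the count was 6002, and 5757 of these were among the 6700. XIST was at 2.58 ± 0.24 and 3.41 ± 1.83, KDM6A at 4.65 ± 0.52 and 4.31 ± 0.54, and EIF2S3 at 10.78 ± 0.38 and 10.34 ± 0.22, with adjusted p-values of 0.641, 0.434 and 0.0967.

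Whether SCNT placentas deviated towards their donor cells was tested with contrasts that share no array. Across 10436 probe sets, which are not independent, SCNT minus AI correlated with fibroblast minus IVP at r = −0.446 (Spearman's rho = −0.427). An exact relabelling of the 6 arrays of the first contrast gave a two-sided p of 0.8, where the smallest possible is 0.1. The correlation was −0.171 without AI replicate 3, which carried fibroblast transcripts. Every relabelling held that array on one side or the other, and another split reached an absolute r of 0.752. No relabelling was run without it, so this p does not settle the donor direction. SCNT minus IVP correlated with fibroblast minus AI at r = 0.139 (rho = 0.139, exact p = 0.5), and between 0.0908 and 0.173 with single arrays left out. The comparison pair, IVP minus AI with fibroblast minus SCNT, had r = −0.737 (rho = −0.767, exact p = 0.3), and −0.441 without AI replicate 3.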

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

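The tests of explanations in this part were all chosen after the results were seen, except the counts over other splits of the arrays, which were planned.

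AI replicate 3 and fibroblast replicate 1 each carried transcripts of both tissues. The fibroblast probe sets of AI replicate 3 stood at a median of 32.8% of their linear level in fibroblast replicates 2 and 3 and its placenta probe sets at 71.2% of their level in IVP placentas, a sum of 104%, and the shares in fibroblast replicate 1 were 69.9% and 32.8%, a sum of 103%. RNA of the other tissue mixed into each sample would give sums close to a whole. The sums of the other arrays ran from 73.9% to 109%, so such a sum is not specific to mixing. In AI replicates 1 and 2, which the choice of probe sets did not use, the fibroblast shares were 0.731% and 0.764%. These are medians close to the lower limit of the scale, where IVP and SCNT placentas stood between 0.591% and 0.699%. In each of the 2 AI arrays 7 of the 16 probe sets were above 4, so the medians do not describe every probe set. An exchange of labels between unmixed samples is argued against, because the placenta probe sets of AI replicate 3 lay a median of −0.53 from those of AI replicates 1 and 2 and not at the level of fibroblasts. An exchange of the 2 mixed samples cannot be judged this way, because the placenta probe sets of fibroblast replicate 1 had a median of 9.18 themselves. At which step a mixture may have arisen stays open, and no biological explanation was tested.

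The 24 matrix genes were lower in SCNT than in AI placentas. Fibroblast RNA in AI replicate 3 is argued against as the whole cause, because the list median was −1.78 without that array with a camera adjusted p of 6.03e-09. However, the list did not pass there with an estimated correlation (adjusted p = 0.761). Over the single alternatives run on the list, its camera or fry adjusted p ran from 3.40e-10 to 0.722. For AI replicates 1 and 2, the matrix genes would need 11.3% and 20.5% of fibroblast RNA. The median of 15 fibroblast probe sets lay below the level those shares predict, with differences of −4.13 in AI replicate 1 and −4.41 in AI replicate 2. The probe sets were split, however. In each of these arrays 7 of all 16 were above 4, with CCL2 at 7.37 in AI replicate 2, so the medians do not describe every probe set. Conceptus sex cannot be told apart from embryo origin: IVP replicate 3, the IVP array with high XIST, had a matrix median −0.82 from that of IVP replicates 1 and 2, and this is a single array. Embryo origin, named by the design, and the amount of connective tissue in the pieces taken stay open and untested.

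The direct comparison of SCNT and IVP placentas, which tests the difference between their effects against AI placentas, singled out 5 probe sets: SERPINB1 at 1.93, ADD3 at −3.38, DEFB4A at −2.30, Bt.15801.1.A1_at at −3.33 and Bt.17073.1.S1_at at 1.71 on the log2 scale. The SCNT mean of Bt.15801.1.A1_at, 3.34, lay under 4, so that level has only an upper bound. The XIST level did not separate the arrays in these: IVP replicates 1 and 2, with XIST as low as in SCNT placentas, lay at least 1.25 from every SCNT array in all 5. The 5 were picked for a difference between these groups beyond their spread, so such a gap was largely fixed in advance. It is therefore no separate test of sex. A sequence difference under a single probe set is argued against for DEFB4A, whose other probe set differed by −1.42 with a 95% interval from −2.09 to −0.74 that overlaps the interval of the first. For ADD3 and SERPINB1 it cannot be told apart from a change in level: the other probe sets differed by −0.94, in an interval from −1.75 to −0.13 that does not reach that of the first, and by 1.29, in an interval from −0.02 to 2.59. A genotype shared with the donor cells stays open: 4 of the 5 lay on the fibroblast side of IVP, but for DEFB4A and Bt.15801.1.A1_at fibroblast replicates 2 and 3 were near the lower limit of the scale (means 2.42 and 2.40), so any decrease would count and these give no support, and embryo origin itself is untested.

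The same comparison singled out 6 gene lists whose shift differed between SCNT and IVP placentas, with median differences of −0.71 for the matrix genes, −0.38 for ribosomal proteins, −0.36 for oxidative phosphorylation, −0.37 for antioxidant defence, −0.49 for WNT and BMP signalling and −0.51 for chemokines and cytokines. None passed with an estimated correlation (adjusted p = 0.833), and none passed with fry.

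The 6 arrays of each comparison can be split in 10 ways, 1 of them real, which is too few for a share under 0.05. The real split called 187 probe sets between SCNT and AI placentas and the highest other split 7. These counts were 1 and 0 between IVP and AI placentas, 5 and 0 between SCNT and IVP placentas, 5450 and 7 between fibroblasts and AI placentas, and 6700 and 0 between SCNT placentas and fibroblasts.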

How the results depend on the processing

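The alternatives that leave out the mixed arrays, AI replicate 3 and fibroblast replicate 1, were chosen after the data were seen. The 187 calls of SCNT vs AI placenta became 1 with no filter (more probe sets tested), 7 with only the 6 arrays compared, 354 with all 12 arrays, 73 with 1 probe set per gene (fewer tested), 665 with the replicate block, 6764 with array weights, 1099 at an unadjusted p and at least 2-fold, 8 without the mixed arrays and 5 also without SCNT replicate 1, and ran from 0 to 3146 with 1 array left out. Quantile normalization gave 257 and median centring 277. The 1 call of IVP vs AI placenta became 2 with no filter, the replicate block or all 12 arrays, 0 with the 6 arrays, 1 probe set per gene or the mixed arrays out, with or without SCNT replicate 1, 2093 with array weights, 350 at an unadjusted p and at least 2-fold, and 0 to 5 with 1 array left out. With no filter the 2 calls did not include that of the main fit, Bt.2120.1.S1_at. Of 15 alternatives followed for that probe set, 10 ended its call. The 5 calls of SCNT vs IVP placenta became 2 with no filter, 3 with 1 probe set per gene, 6226 with array weights, 331 at an unadjusted p and at least 2-fold, and 3 to 1757 with 1 array left out. The array weights did not converge, so those counts carry no weight. Fibroblast vs AI placenta went from 5450 calls to 3383 with the filter at 6 and 3123 with 1 probe set per gene (fewer tested in both), 3507 with a fold of at least 2 as well and 3582 at an unadjusted p with that fold. SCNT placenta vs fibroblast went from 6700 to 4118 and 3795 with the filter at 6 and 1 probe set per gene. The remarks on more or fewer probe sets tested are context only, and no cause of a changed count was tested.

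Whether the replicate numbers pair the arrays stays open. Deviations of arrays with the same number correlated between −0.12 and −0.01 for AI and IVP, −0.08 and 0.09 for AI and SCNT, 0.09 and 0.29 for IVP and SCNT, −0.06 and 0.34 for AI and fibroblasts, and −0.14 and 0.04 for SCNT and fibroblasts, and not every array correlated best with its own number. The arrays that did so numbered 0, 1, 2, 2 and 0 in the same order. Arrays with different numbers correlated at up to 0.20 for IVP and SCNT and 0.21 for AI and fibroblasts. With the replicate block the 5 counts were 665, 2, 5, 5355 and 6595, and 41 of the 43 list shifts passed.

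All 43 list shifts kept their direction under every alternative run on the lists, but 0 passed with an estimated correlation. With fry 25 of the 43 passed and 18 did not. Fry passed 3 lists in SCNT vs AI placenta, 0 in IVP vs AI placenta and 0 in SCNT vs IVP placenta. The donor direction, r = −0.446, was −0.156 without the mixed arrays, −0.223 also without SCNT replicate 1, and −0.554 to −0.171 with 1 array left out. The correlation of the SCNT and IVP deviations ran from 0.647 to 0.782 with 1 array left out, but its value for unchanged groups moves with the arrays too: simulations gave 0.446 to 0.448 with 3 AI arrays and 0.599 to 0.601 with 2, and the excess was 0.0911 to 0.334. Of 141 calls of single genes in a comparison that were followed over the alternatives, 31 did not pass with no filter, 32 without some array and 15 of 124 without the mixed arrays, and quantile normalization ended none. Signs turned for TPM1 in SCNT vs AI placenta with its other probe set (0.30), for EIF2S3 in SCNT vs AI placenta without SCNT replicate 1 (−0.014, with up to 0.37 without another array, and −0.019 with the mixed arrays out too) and with its other probe set (−0.23), in IVP vs AI placenta without IVP replicate 2 (0.038, down to −0.20 without another) and in SCNT vs IVP placenta with its other probe set (−0.17), and for XIST in SCNT vs IVP placenta without IVP replicate 3 (0.22, down to −2.90 without another) and in SCNT placenta vs fibroblast without fibroblast replicate 1 (0.23, down to −1.37 without another, and 0.094 with all 3 arrays out); none of these passed. Signal close to the lower limit of the scale bounds the folds of dim genes.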

Other observations

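The values in this part were looked at after the data were seen, and no explanation was tested for them. SCNT replicate 2 stood apart in its globins. HBE1, an embryonic globin, was at 13.06 in SCNT replicate 2 and between 5.81 and 10.53 in the other 8 placentas, while HBB, the adult beta globin, was at 9.02 there and between 12.21 and 13.82 in the others. These paralogs are similar in sequence, so their probe sets can share signal. Over the 7 erythroid genes the median difference between SCNT and AI placentas was −1.27, which did not pass (camera adjusted p = 0.0740), and without AI replicate 3 it was −1.84, which passed with the preset correlation (adjusted p = 0.0187) but not with an estimated correlation (adjusted p = 0.761).

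IGF2, the imprinted fetal growth factor, was lower by 1.65 in SCNT than in AI placentas without passing (adjusted p = 0.0837), at 9.10 ± 0.17 in IVP and 8.34 ± 1.17 in SCNT placentas (SD, n = 3), and was at the lower limit of the scale in fibroblast replicates 2 and 3. CSH2, placental lactogen, was at 12.40 ± 0.62 in AI, 12.86 ± 0.07 in IVP and 12.52 ± 0.68 in SCNT placentas.

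SCNT replicate 1 differed from the other arrays in its scale. Its 99th percentile was 10.61, against 10.85 to 11.04 in the other 11 arrays, and its bacterial spike-in probe sets for bioB averaged 6.58, against 4.77 to 5.75.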
